A study of Rattus norvegicus with 9 samples.

How the data were processed

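RNA was sequenced from the left testis of Sprague Dawley rats in 3 groups of 3 libraries, taken from the titles of the samples: sham-operated control rats, rats with an experimental varicocele given saline (varicocele, VC), and rats with a varicocele given a polysaccharide from the root of Morinda officinalis (VC+MOP). Per the labels' protocols, total RNA was fragmented and reverse transcribed with random primers, and the second strand was marked with dUTP, which keeps the strand of origin. The labels do not say outright that each library came from a different rat, so p-values measure the spread between these libraries.

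The deposited values are a transcript abundance signal on a linear scale, with 1 column per library per the file headers. The header names no unit, and the values do not tell FPKM from TPM. The submitters' processing notes name cutadapt, HISAT2 2.0.5 and StringTie 1.3.1c with no role or order. They name hg19, a human genome build, while the 19532 transcripts of the table carry rat Ensembl identifiers. The rat annotation release is not given in the sources used here. In the deposited grouping every transcript had a mean of at least 0.5 in at least 1 of the 3 groups: the smallest such highest group mean was 0.5001, and 0 transcripts fell below 0.5. In the other splits of the 9 libraries into 3 groups of 3, out of 280 in all, between 99 and 236 transcripts fell below it. A filter on the means of these 3 groups before deposit would give this; no such filter is given in the sources used here.

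None of the transcript identifiers (0 of 19532) could be paired with a gene, because the gene table used here lists RefSeq accessions and no Ensembl identifiers. Transcripts are therefore reported by identifier, their genomic positions are not given, and coding and long noncoding transcripts could not be told apart. The gene lists for testis cell types and stress pathways, the comparison of coding with noncoding transcripts and the sums per gene that were fixed before the data were examined could not be run. At most 2 transcripts that rose and 2 that fell were named per comparison, those with the smallest p among transcripts past the threshold. This replaced the fixed rule, which called for gene symbols.

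Sequencing depth is unknown. Values above 0 went down to 0.000008, and among transcripts below 0.1 in both libraries of a pair at most 10% had ratios within the same 2% window in any of the 36 library pairs, so whole reads could not be recovered. No counting interval or detection floor is given.

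Transcripts at 0.5 or more in at least 3 of the 9 libraries were kept (19185; 347 were left out). The values were taken as log2(value + 0.5) with no further scaling, so a fold change is on that scale and understates the change of rare transcripts. limma 3.58.1 in R 4.3.3 fitted 1 linear model to all 9 libraries, with the group as its only term, 6 residual degrees of freedom and an empirical Bayes variance trend (limma-trend). A transcript counted as changed at a Benjamini-Hochberg adjusted p below 0.05 over the 19185 transcripts, separately for each of the 3 comparisons, and all tests were two-sided. Because the values are not counts, no count model was used.

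The fit was tested on simulated data: 200 transcripts were changed by a known factor among 19185 with each transcript's own mean and within-group spread. For varicocele against control it recovered 39.5% of 1.5-fold changes, 70.5% of 2-fold changes and 91.5% of 4-fold changes. For VC+MOP against varicocele these shares were 43%, 70% and 92.5%, and for VC+MOP against control 31.5%, 68% and 88%. Among transcripts above the median abundance 88.8%, 90.6% and 88.2% of 2-fold changes were recovered in the 3 comparisons in that order, and among those below it 49.5%, 46.8% and 46.9%.

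The alternatives were pseudocounts of 0.1 and 1, other filters on low values, median-of-ratios and quantile scaling, robust variances, library weights, fits to the compared groups alone, the replicate number as a block, other thresholds, and leaving out each library in turn. Correlations of fold changes that share libraries were set beside 200 simulations with no effect, and overlaps of lists beside 50. An F test over the 3 groups, and tests of each of the 84 possible sets of 3 libraries against the other 6, were added after seeing the data, as were the overlap of calls in other splits and the split of the varicocele libraries between comparisons. Figures were drawn with matplotlib 3.10.9.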

Results

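Left testes were profiled by RNA sequencing in a rat model of varicocele, the dilation of the veins that drain the testis. The dilation was induced by partly ligating the left renal vein, and sham-operated rats served as controls. From 8 weeks after the operation, rats with a varicocele received by gavage either about 2 mL of saline per day or 300 mg per kg per day of Morinda officinalis polysaccharide, a carbohydrate fraction of a medicinal root, for 4 weeks. The data comprised 3 libraries per group and 19532 transcripts. The abundances of each library summed to between 478800 and 486011, and between 213 and 258 transcripts were listed at 0 per library.

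Libraries of different groups were nearly as alike as libraries of the same group. Correlations of log2 abundance across transcripts were 0.9698 to 0.9719 for the 9 pairs of libraries within a group and 0.9681 to 0.9715 for the 27 pairs between groups. Such correlations follow the range of abundance across transcripts and cannot exclude changes of single transcripts. The first principal component held 14.1% of the variance and the eighth 11.3%, so no single axis dominated. On the first, control 1 and 2 stood at 30.45 and 32.57 and control 3 at -6.7. The varicocele libraries lay between -15.26 and 3.69 and the VC+MOP libraries between -23.17 and -6.37. The median coefficient of variation within groups was 31.4% for transcripts with a mean below 1, 16.2% from 1 to 5, 8.4% from 5 to 20 and 4.1% at 100 or more. The 100 most abundant transcripts, all with a mean of at least 410, held no transcript past the threshold in any comparison, and their median absolute log2 fold change was 0.019 for varicocele against control and 0.045 for VC+MOP against varicocele.

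Varicocele against control asked what the venous ligation changed in the testis. The labels list a saline gavage for the varicocele rats and none for the controls, so this comparison does not separate ligation from gavage. Of 19185 transcripts tested, 3 changed, of which 1 rose and 2 fell (limma, adjusted p below 0.05). ENSRNOT00000061032 rose from 1.32 ± 0.137 in control to 3.88 ± 0.145 in varicocele testes (SD, n = 3 each), a log2 fold change of 1.27 ± 0.09 (SE, limma adjusted p = 0.00461). ENSRNOT00000038780 fell from 8.04 ± 1.16 to 3.01 ± 0.0452, a log2 fold change of -1.27 ± 0.11 (SE, limma adjusted p = 0.00975). ENSRNOT00000023376 was listed at 3.95, 4.95 and 3.77 in the control libraries and at 0.001, 0.0016 and 0.0006 in the varicocele libraries (limma adjusted p = 9.78e-05), and no fold is given against values so near 0. In the VC+MOP libraries ENSRNOT00000061032 stood at 3.87 ± 0.104 and ENSRNOT00000038780 at 2.89 ± 0.175, next to the varicocele levels.

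**Figure D1:**
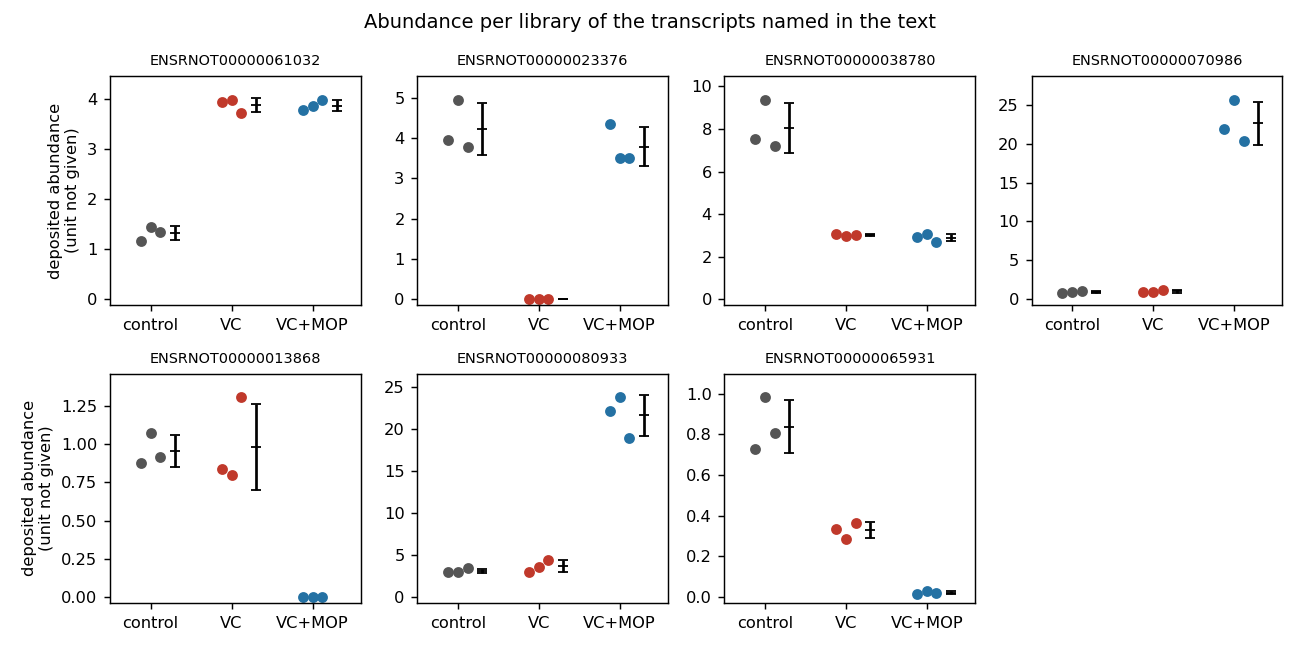
Deposited abundance (vertical axis, linear, unit not given) of the 7 named transcripts in each library of the control, VC and VC+MOP groups. Points are libraries, and the bar beside them is the mean ± SD of 3 libraries, left out where all are listed at 0; ENSRNOT00000070986 stands near 1 in the 6 control and VC libraries and above 20 in the VC+MOP libraries.

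Most transcripts were bounded close to their control level. The median absolute log2 fold change was 0.084 with a median SE of 0.127, and the 95% interval lay within a 2-fold change either way for 16782 of 19185 transcripts (87.5%). Among the 10101 transcripts with a mean of at least 5, it lay within 2-fold for 95.1% and within 1.5-fold for 88.7%. An unadjusted p below 0.05 was reached by 885 transcripts, where 959 would be reached with no effect, and 124 of these differed by at least 2-fold, 59 of them higher and 65 lower in varicocele. Leaving out 1 library gave between 2 and 10 changed transcripts: 7 and 8 without control 2 and 3, 6 and 10 without varicocele 1 and 3, and 5, 7 and 5 without VC+MOP 1, 2 and 3. ENSRNOT00000038780 did not pass without control 1 (limma adjusted p = 0.0651) or without varicocele 2 (limma adjusted p = 0.0569), in a range from 0.00955 to 0.0651 over the 9 libraries left out.

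VC+MOP against varicocele asked what the polysaccharide changed in testes with a varicocele. Of 19185 transcripts 4 changed, of which 3 rose and 1 fell (limma, adjusted p below 0.05). ENSRNOT00000070986 rose from 1.01 ± 0.209 in varicocele to 22.6 ± 2.75 in VC+MOP testes (SD, n = 3 each), a ratio of means of 22.5 and a log2 fold change of 3.94 ± 0.13 (SE, limma adjusted p = 1.64e-05). ENSRNOT00000023376, near 0 in the varicocele libraries, was listed at 4.35, 3.51 and 3.5 in the VC+MOP libraries (limma adjusted p = 7.01e-05). It did not differ past the threshold between VC+MOP and control (log2 fold change -0.14 ± 0.13, SE, limma adjusted p = 0.83). ENSRNOT00000013868 fell: it was listed at 0.84, 0.8 and 1.31 in the varicocele libraries and at 0 in each VC+MOP library (limma adjusted p = 0.0473).

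The median absolute log2 fold change was 0.097, and the 95% interval lay within 2-fold for 16730 transcripts (87.2%). At an unadjusted p below 0.05 stood 1205 transcripts, where 959 would be reached with no effect, and 121 of them differed by at least 2-fold. Leaving out 1 library gave between 3 and 12 changed transcripts: 7 without varicocele 1, and 9, 9 and 12 without VC+MOP 1, 2 and 3. ENSRNOT00000013868 lost its call whichever library was left out (limma adjusted p between 0.0537 and 0.168).

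**Figure D2:**
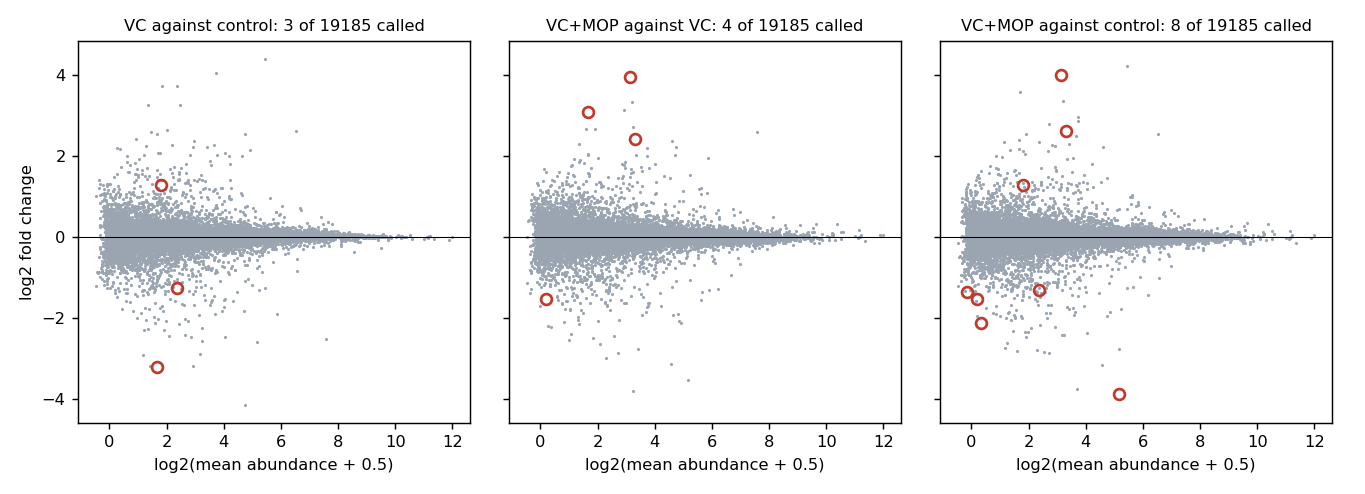
Log2 fold change (vertical axis) against log2 of the mean abundance plus 0.5 (horizontal axis) for the 19185 transcripts tested in the 3 comparisons. Grey points are transcripts and red circles those with a limma adjusted p below 0.05, of which there were 3, 4 and 8.

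VC+MOP against control asked how far treated testes stood from sham-operated ones, and gave 8 changed transcripts, 3 higher and 5 lower in VC+MOP (limma, adjusted p below 0.05). With no gavage listed for the controls, this comparison does not separate ligation, gavage and polysaccharide. ENSRNOT00000070986 rose from 0.947 ± 0.0877 in control to 22.6 ± 2.75 (limma adjusted p = 1.48e-05) and ENSRNOT00000080933 from 3.1 ± 0.258 to 21.6 ± 2.43 (SD, n = 3 each; limma adjusted p = 0.000305). ENSRNOT00000038780 fell from 8.04 ± 1.16 to 2.89 ± 0.175 (limma adjusted p = 0.00532). ENSRNOT00000065931 fell from 0.838 ± 0.129 in control to 0.0206 ± 0.00821 in VC+MOP testes and stood at 0.328 ± 0.0402 in varicocele testes (SD, n = 3 each; limma adjusted p = 0.0335). In 3 of the 8 changed transcripts all VC+MOP libraries were listed below 0.05. Means over all libraries ran from 0.4 to 35.14 among the 8, and the transcript with the highest mean was lower in VC+MOP. At an unadjusted p below 0.05 stood 1265 transcripts, and 133 of them differed by at least 2-fold. Leaving out 1 library gave between 6 and 15 changed transcripts, with 15 without VC+MOP 3, and ENSRNOT00000065931 lost its call whichever library was left out (limma adjusted p between 0.0634 and 0.13).

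Across the comparisons 9 transcripts changed at least once. Both varicocele groups, each with a gavage listed, differed from control in the same direction in 2 of them (independent lists of the same lengths would share 0.0013). VC+MOP differed from both other groups in the same direction in 3, among them ENSRNOT00000070986 (independent lists would share 0.0017). ENSRNOT00000023376 was the 1 transcript called in opposite directions, lower in varicocele against control and higher in VC+MOP against varicocele (independent lists would share 0.00063). Each pair of comparisons shares a group, so independent lists are not the value with no effect. In 99 other splits of the 9 libraries into 3 groups, 68.4% of the pairs of comparisons shared at least 1 called transcript, 44.4% at least 2 and 20.2% at least 3, with up to 8 shared.

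Whether the polysaccharide moved transcripts opposite to varicocele was asked across all 19185 transcripts. The fold changes of VC+MOP against varicocele and of varicocele against control had a Pearson r of -0.477 (Spearman rho -0.406) across transcripts, which are not independent replicates. Because the varicocele libraries enter both with opposite sign, simulations with no effect gave a median r of -0.498 (95% of values between -0.535 and -0.459). The covariance was -0.041, against a simulated median of -0.042 (between -0.048 and -0.037). At an unadjusted p below 0.05 in both comparisons, 224 transcripts had opposite signs and 7 the same sign, where simulations with no effect gave medians of 245 and 5 and independent lists 28 each. With the 3 varicocele libraries split between the comparisons, 1 to one and 2 to the other, r lay between 0.001 and 0.022 over the 6 ways to do so. No opposition beyond that of the shared libraries was detectable.

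**Figure D3:**
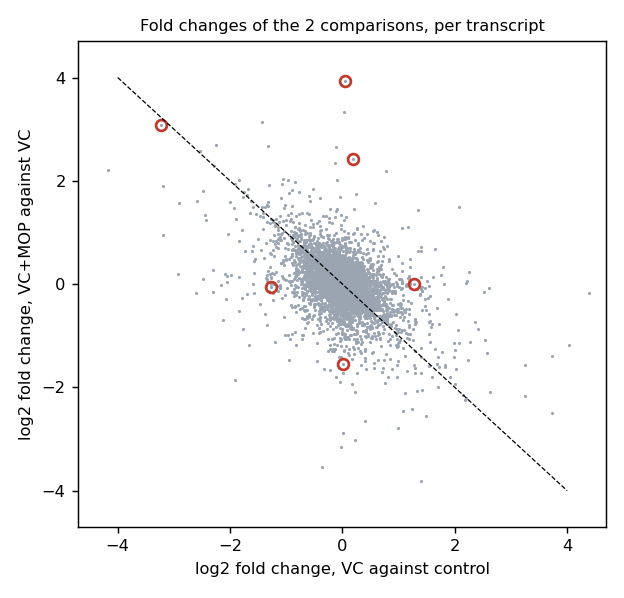
Log2 fold change of VC+MOP against VC (vertical axis) plotted against that of VC against control (horizontal axis) for each transcript. Red circles mark transcripts called in either comparison and the dashed line equal and opposite changes; the downward tilt of the cloud (r = -0.477) lies within the range simulated with no effect.

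In a test added after the data were examined, each group was set against the other 6 libraries, beside the 81 sets of 3 libraries that mix groups. Control differed from the rest in 6 transcripts, varicocele in 7 and VC+MOP in 6 (limma, adjusted p below 0.05), and the mixed sets in a median of 2 and at most 10. Among transcripts with a mean of at least 0.5 over the 9 libraries, which a filter on the means of any grouping would keep, these counts were 2, 3 and 4, and the mixed sets again had a median of 2 and at most 10. At an unadjusted p below 0.05, 966 transcripts differed for control, 849 for varicocele and 1496 for VC+MOP, and the mixed sets ran from 509 to 1697 with a median of 877. A mixed set can hold 2 libraries of the same group and so carry part of any group effect. The range of the mixed sets is therefore not that of no effect, and lying within it does not show that a group effect is absent. The 1496 transcripts of VC+MOP comprised 695 that were higher and 801 that were lower, with a median absolute log2 difference of 0.23.

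**Figure D4:**
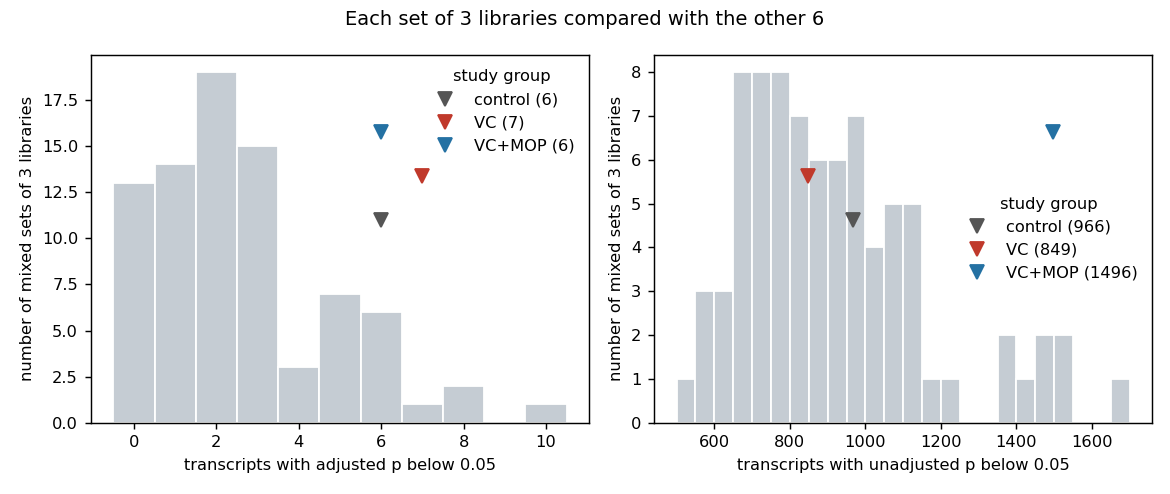
Number of transcripts that differ between a set of 3 libraries and the other 6, at an adjusted p (left) or unadjusted p (right) below 0.05 (horizontal axes), by limma. Grey bars count the 81 sets that mix groups (vertical axes) and triangles, whose height has no meaning, mark the study groups. All 3 groups lie within the range of the mixed sets, some of which hold libraries of the same group and so carry part of any group effect.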

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

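The low number of changed transcripts held under every setting run that kept an adjusted p below 0.05: between 1 and 15 of the transcripts tested changed in any comparison. Varicocele against control gave 3 in the report, 8 when the 2 groups were fitted alone, 5 at an adjusted p below 0.10 and 124 at an unadjusted p below 0.05 with at least 2-fold. VC+MOP against varicocele gave 4 in the report, 10 at an adjusted p below 0.10, 121 at the unadjusted threshold, and 2 without transcripts listed below 0.05 in a whole group. VC+MOP against control gave 8 in the report, 5 with a pseudocount of 1 or quantile scaling, 4 with a mean of at least 1, 133 at the unadjusted threshold, and 4 without transcripts listed below 0.05 in a whole group. That last filter and the filter on a mean of at least 0.5 were chosen after seeing the data. Leaving out 1 library at a time gave 2 to 10, 3 to 12 and 6 to 15 changed transcripts in these comparisons, the highest without varicocele 3, VC+MOP 3 and VC+MOP 3. Of the 3, 4 and 8 in the report, these lists kept 2 to 3, 3 and 4 to 6, so membership changed as well as length. The cause of this variation was not tested. With the replicate number as a block, which did not pair the libraries (correlations of same-numbered deviations from -0.059 to 0.037, and 3 of 9 libraries closest to their own number), 1, 3 and 4 transcripts changed in the 3 comparisons. Of 130 refitted values of the named transcripts 105 stayed past the threshold, 25 did not and 0 changed direction. The correlation of the fold changes of treatment and varicocele was -0.439 for transcripts with a mean of at least 5 (simulated with no effect, -0.501) and between -0.58 and -0.414 without single libraries (simulated with no effect, between -0.602 and -0.448). With the varicocele libraries split between the comparisons, a setting chosen after seeing the data, it had a median of 0.007, since no library then enters both. The gene lists, sums per gene and count models were not run, because the table holds no gene names and no counts, and transcripts as deposited were already the level tested. Read depth is unknown. In simulated data fewer 2-fold changes of value + 0.5 were recovered below the median abundance (46.8% to 49.5% by comparison) than above it (88.2% to 90.6%). The shrinking of folds by the pseudocount is not part of this difference, because the change was made after it was added. Whether depth or the pseudocount sets the spread of rare transcripts was not tested.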

Other observations

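The F test, the sets of 3 libraries and the splits of the libraries were chosen after the calls were seen but before their own values were; the tests on transcripts set apart between libraries, on called transcripts with no group near 0, on the filter among called transcripts and in the control and varicocele groups, and on the 280 splits were chosen after the results they bear on were seen.

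Over the 19185 transcripts, 383 had 1 library set apart from the other 8 by more than 2-fold, 97 with that library above and 286 with it below. Each library accounted for between 35 and 58 of them, and 134 had a mean of at least 5. Normal noise with each transcript's own spread gave 424. That spread already holds the libraries set apart, so this count cannot show whether they exceed noise.

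An F test over the 3 groups called 7 transcripts, 32 of 100 splits of the 9 libraries called as many and the highest other split called 17, so chance is not excluded. Against the other 6 libraries, control had 6 calls (13 of 84 sets of 3 had as many), varicocele 7 (5 of 84) and VC+MOP 6 (13 of 84), with up to 10 in another set, so chance is not excluded there; at a mean of at least 0.5 these counts were 2, 3 and 4, reached by 52, 33 and 17 of 84 sets, so the filter on group means stays open for them. For the 9 transcripts called between groups the tables argue against that filter as the whole cause, since 11.1% had a mean below 0.5 and any grouping would keep the others. Values near 0 in a whole group cannot give the 5 calls with no group below 0.05. They stay open for the other 44.4%, against 0.35% of the transcripts tested. Among transcripts with a mean of at least 0.5, 25 of 84 sets had at least as many near 0 in that set alone as the 2 of the highest group. That limit leaves out ENSRNOT00000065931, a call near 0 in VC+MOP with a mean of 0.396. Transcripts that set some libraries apart from the others whatever their group may account for the called transcripts. In 30 of 84 sets of 3 libraries, at least as many transcripts stood apart by more than 2-fold as the 4 of the highest group. That count does not ask whether a transcript is switched on or off, or whether single libraries vary. The 5 calls with no group below 0.05 were not off in any group. An effect of the operation or the polysaccharide stays open. A shift of reads between transcripts of 1 gene was not tested because no transcript was paired with a gene.

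For the pairs of groups, 10 splits of 6 libraries are too few for a share under 0.05. Varicocele against control called 3 with 7 in the highest other split, VC+MOP against varicocele 4 with 7, and VC+MOP against control 8 with 9, and 7, 3 and 3 of the 10 splits called as many. At an unadjusted p below 0.05 (limma) the study's grouping gave 885, 1205 and 1265 transcripts, and the highest other split 1255, 1095 and 1217. With at least 2-fold it gave 124, 121 and 133, and the highest other split 121, 124 and 133. Among transcripts with a mean of at least 0.5 these were 108, 117 and 121 against 119, 123 and 132. Where the study's grouping stood highest, 10 splits cannot tell this from chance.

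At an unadjusted p below 0.05 with at least 2-fold, 94 transcripts set control apart from the other 6 libraries, 88 varicocele and 99 VC+MOP, where the mixed sets had a median of 77 and at most 100. A candidate explanation is the deposited filter on group means, which would favour transcripts that differ between these groups. Among transcripts with a mean of at least 0.5, which any grouping would keep, control had 87, reached by 12 of 84 sets against 4 before, and varicocele had 80, reached by 28 against 9 before, so the filter stays open for both. VC+MOP had 97, reached by 3 of 84 sets, which argues against the filter as the cause of its count. Of the 280 splits of the 9 libraries, 20 had a highest group with at least 99, the highest other being 100, so chance is not excluded.

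VC+MOP had 1496 transcripts at an unadjusted p below 0.05 against the other 6 libraries, where 959 would be reached with no effect, with a median abundance of 11.08 against 5.71 over the transcripts tested. The tables argue against a difference in scale between libraries, since median-of-ratios size factors gave 1496 and 4 of 84 sets had as many. They argue against the filter on group means, since 1462 were found at a mean of at least 0.5 and 4 of 84 sets had as many. Of the 280 splits, 36 had a highest group with as many and the highest other had 1697, so chance is not excluded. Other sets and splits can keep libraries of the same group together and so carry part of any effect, so an effect is not excluded either. A small shift of many transcripts under the polysaccharide may exist as a hypothesis, which these libraries do not separate from the spread between libraries.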
